A study of Homo sapiens with 94 samples.

How the data were processed

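RNA from cell-free saliva supernatant of 63 gastric cancer and 31 normal samples was measured on 1-colour Affymetrix arrays, with 1 array per sample. Saliva was collected without stimulation and spun down, and total RNA was extracted from the supernatant with a Qiagen column kit and labelled with biotin, per the labels' protocols. The deposited values were produced with Affymetrix Expression Console, per the submitters' processing notes. Its version and the summarization algorithm were not given in the sources used here. The deposited table holds the authors' linear intensity values of 54675 probesets. Each array's mean without the lowest and highest 2% of probesets lay between 500.01 and 500.107, so the arrays had been scaled to 1 common trimmed mean, and their distributions were not otherwise matched. The plan fixed beforehand assumed log2 values and provided for linear ones. The values were linear, so log2 was taken first. The lowest intensity was 1.68, and no floor or pseudocount was needed.

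The 62 Affymetrix control probesets and 95 probesets of sex-linked transcripts were left out of the tests, which left 54518 probesets with no filter on dim ones. Gene names came from the platform annotation, which can be old. Of the probesets other than controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none, and no gene was named from a probeset with several. Symbols of 41037 probesets were updated through the gene identifier in the reference. For tests on genes, the probeset with the highest mean over all arrays was taken, which gave 19740 genes. No genome coordinates were used.

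Groups were taken from the disease state in the labels. The main comparison was limma's moderated test, two-sided, with lmFit and eBayes on the 63 and 31 arrays without covariates, and with Benjamini-Hochberg adjustment. A probeset was called at an adjusted p under 0.05. The labels were taken to describe separate persons. They give no batch or date, and number the samples within each group. Some sample names carry a suffix whose meaning is not given, so a repeat cannot be excluded for them. Without these, 60 gastric cancer and 30 normal samples were left, and limma made 0 calls. The shared numbers did not pair the samples: over 31 shared numbers the correlation of deviations from the group means had a median of 0.0124, and 6 pairs exceeded 0.1.

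A total of 24 gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with an estimated correlation beside it, and with fry. They covered cell types whose RNA saliva could hold, transcripts of gastric tissue and tumours, general cell programmes and 1 panel of 3 mRNAs that the study put forward from these samples. The olfactory receptor list, whose genes are not thought to be transcribed in saliva, served as background. The 95th percentile of the mean levels of its probesets, a log2 intensity of 8.41, was taken as the background level. Members of a list were also adjusted over the list alone. Each array's mean log2 intensity over a list was compared between groups by a two-sided permutation test with 100000 resamples, with intervals from a linear model. Areas under the ROC curve give the probability that a gastric cancer array exceeds a normal one, with 2000 bootstraps for the 95% interval. A classifier was assessed by 5-fold cross-validation repeated 20 times with 30 probesets chosen inside each training part, and labels were permuted 100 times for its null. Array measures included the hybridization control spikes, which are bacterial and phage transcripts added in fixed amounts after labelling, and the log2 difference between 3-prime and 5-prime control probesets of ACTB and GAPDH, a sign of RNA shortening.

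The genes named were fixed by rule. These were the genes called with the largest changes or, with none called, the 5 genes with the smallest p in each direction. The panel was added, with up to 4 members with the smallest p of each list with a called member or a camera adjusted p under 0.05 and up to 2 members of each other list. Unannotated loci were passed over. Genes outside this rule are said to be so where they appear.

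The groups, designs, gene lists, naming rule and a first set of other settings were fixed before the data were examined. These settings covered normalization, filters, array weights, variance priors, other tests, covariates and a block on the sample number. Others were added after seeing the data: those with the hybridization spikes, those with the sample number as a covariate or as a limit on the samples, those without arrays with low abundant transcripts, and their combinations. The per-probeset test was tested on simulated data with the real arrays' spread. It recovered 20% of probesets changed by 1 log2 unit, 64% at 1.5, 96% at 2 and 100% at 3, with 50 probesets at each size among 54518, and it made 2 false calls. Group means had been removed and the labels permuted, so the simulated groups lacked the array-level differences of the real ones. The number of false calls therefore does not carry over to the real comparison. The number of arrays limits the precision. R 4.3.3 with limma 3.58.1 and version 1.17.8 of the data.table package and, for plots, Python 3.11.15 with matplotlib 3.10.9 were used.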

Results

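RNA in cell-free saliva supernatant was profiled in 63 gastric cancer and 31 normal samples to look for transcripts that tell the groups apart. Saliva carries RNA of shed oral squamous epithelium, of white blood cells and of the salivary glands. The brightest gene lists were abundant transcripts common to most cells, with a mean log2 intensity of 13.8, ribosomal proteins at 13.7, neutrophil markers at 12.9 and squamous epithelial genes at 12.7. Markers of gastric epithelium averaged 8.06, below the background level of 8.41. In all, 13358 of 54518 probesets, or 24.5%, had a mean above that level. Arrays resembled each other only loosely, with a median correlation of 0.394 between pairs and a highest of 0.669.

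No transcript differed between gastric cancer and normal saliva at an adjusted p under 0.05 by limma, where the smallest adjusted p was 0.0978. At an unadjusted p under 0.05, 6472 probesets differed, of which 4791 were higher and 1681 lower in gastric cancer, against 2726 expected by chance. The rank-sum test called 1 probeset and Welch's test on the 63 and 31 arrays called 4. These named PPP4R3B, a phosphatase subunit, by both tests at a log2 difference of -1.14, and EDEM1, a factor of protein quality control in the endoplasmic reticulum, by Welch's test at -1.31. The other 2 probesets of Welch's test carried no gene name, and all of these were singled out after their values were seen. In 9 arrays, 6 of gastric cancer and 3 normal, the mean over abundant transcripts lay below 11.89, over 1.5 interquartile ranges below the lower quartile. Without them, a choice made after seeing the data, limma called 103 probesets, 45 higher and 58 lower, and with the hybridization spike level as a covariate beside that choice it called 0. Of the 76 named probesets 14 were among the 103, those of TMPRSS11B, NUDT19, ELL2, EPB41L3, BAG3, WDR3, GSK3B, CDC42BPA, ZNF607, CACNA2D3, DSP, PERP, EMP1 and SPINK7. The direction of the unadjusted differences followed brightness. Above the background level 446 probesets were higher and 1307 lower, with a median log2 difference of -0.103, and at or below it 4345 were higher and 374 lower, with a median of 0.251. The share of higher ones was 74% with the values as deposited and 46.6% after quantile normalization. With arrays scaled to their hybridization spikes it was 2.75%, with 231 higher and 8165 lower. The median log2 difference over all probesets was 0.178 as deposited, 0.0103 after quantile normalization and -0.293 with arrays scaled to their hybridization spikes.

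The lower transcripts with the smallest p had normal means of 9.95 to 13.16, above background, and 1 of the 5, NUDT19, had a gastric cancer mean of 8.13, below it. TMPRSS11B, a membrane serine protease, had a log2 intensity of 11.24 ± 2.1 (SD, n = 63) in gastric cancer and 13.16 ± 2 (SD, n = 31) in normal saliva, a log2 difference of -1.92 (SE 0.42). It lay below the normal median in 53 of 63 cancer samples, with an area under the ROC curve of 0.236 (95% interval 0.135 to 0.347). ELL2, a transcription elongation factor, differed by -1.56 (SE 0.36), with 59 of 63 cancer samples below the normal median. NUDT19, a hydrolase, differed by -1.82 (SE 0.41), EPB41L3, a membrane skeleton protein, by -1.52 (SE 0.36), and BAG3, a co-chaperone, by -1.56 (SE 0.37). The higher transcripts with the smallest p were dim, with normal means of 5.71 to 6.82. WDR3, a ribosome biogenesis factor, had a log2 intensity of 7.47 ± 1.81 (SD, n = 63) in gastric cancer and 5.71 ± 1.65 (SD, n = 31) in normal saliva, a difference of 1.75 (SE 0.37), with both means below background. The kinase gene GSK3B differed by 1.76 (SE 0.4), the kinase gene CDC42BPA by 1.69 (SE 0.39), the zinc finger gene ZNF607 by 1.64 (SE 0.37) and the calcium channel subunit gene CACNA2D3 by 1.54 (SE 0.35). All of these 10 genes had an adjusted p of 0.0978 by limma and were not called. Areas of genes picked in the same samples are optimistic.

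Transcripts of desmosomes, the junctions that hold epithelial cells together, were lower in gastric cancer saliva. Adjusted over the list alone, 4 of 12 measured members fell, none rose and 8 did not pass. Over all probesets none passed. The plaque protein gene DSP, PERP and the cadherins DSG3 and DSC2 fell, with log2 differences of -1.77 (SE 0.42), -1.51 (SE 0.46), -1.15 (SE 0.37) and -0.75 (SE 0.3). These are the brightest probesets of each gene, and 3 of 5 PERP and 3 of 4 DSC2 probesets were lower; the DSG3 mean in gastric cancer, 8.18, was below background. DSP lay below the normal median in 49 of 63 cancer samples. The list's median difference was -0.222, against 0.096 over all genes, and camera's adjusted p was 0.00168. This call held with an estimated correlation (adjusted p = 0.0204), and of the 10 lists called it was the only one that did. The list's estimated correlation was 0.0175, close to the preset 0.01, so the 2 tests are nearly the same for it. For the other lists called the estimate was 0.0773 to 0.706. The desmosome list's mean level was 8.995, against a background level of 8.41. The means of DSP, PERP and DSC2 were 9.98 or higher in both groups, so the 8 members that did not pass averaged near background. Lists below background also had low estimates, with 0.0146 for platelets and 0.0251 for T and NK cells. A low estimate can thus go with dim members, and holding this call does not rank the desmosome fall above that of squamous genes. The mean over the list was 8.84 ± 0.553 (SD, n = 63) in gastric cancer and 9.31 ± 0.5 (SD, n = 31) in normal saliva. That difference of -0.465 (95% interval -0.698 to -0.231) had a permutation p of 0.00015, or 0.0036 adjusted over 24 lists, and was -0.365 (95% interval -0.601 to -0.128) with the hybridization spike level as a covariate. In a division by sample number chosen after seeing the data, cancer samples that the labels number 1 to 31 differed from normal by -0.583 (95% interval -0.855 to -0.311) and the other 32 by -0.35 (95% interval -0.608 to -0.0928). The camera call was lost when the test was limited to probesets above background, where the list's shift was -0.342. With the estimated correlation the adjusted p was 0.0418 with the spike level as a covariate and 0.115 with the sample number as one, where the shift was -0.425 against -0.318 in the main comparison. Without the 9 low arrays it was 0.0521, with a difference of means of -0.456 (95% interval -0.69 to -0.221).

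Genes of the keratinized and suprabasal squamous layers, the outer oral lining, did not pass as a list beyond camera's preset correlation. Adjusted over the list alone, 10 of 26 measured members fell, none rose and 16 did not pass, and over all probesets none passed. Those that fell included EMP1, a membrane protein of epithelia, with a log2 difference of -2.03 (SE 0.57) at its brightest probeset, while 4 of its 6 probesets were higher in gastric cancer. SCEL, a cornified envelope precursor, was at -1.42 (SE 0.47) with 3 of 4 probesets lower, IVL, the envelope protein involucrin, at -1.06 (SE 0.36) and EVPL, envoplakin, at -1.05 (SE 0.34) with a gastric cancer mean of 7.84, below background. In all, 24 members were lower and 2 higher, with a median of -0.711. Camera's adjusted p was 9.33e-11, and the call was lost with an estimated correlation (adjusted p = 0.268); fry, which tests against no change, gave an adjusted p of 0.107. The mean over the list was 12.49 ± 1.63 (SD, n = 63) in gastric cancer and 13.24 ± 1.45 (SD, n = 31) in normal saliva. The difference of -0.746 (95% interval -1.43 to -0.0608) had a permutation p of 0.0331, or 0.12 adjusted over the lists, and was -0.247 (95% interval -0.88 to 0.385) with the spike level as a covariate. Without the 9 low arrays it was -0.754 (95% interval -1.22 to -0.291), and camera's adjusted p with an estimated correlation was 0.0997. In the same division by sample number, cancer samples 1 to 31 differed from normal by -1.36 (95% interval -2.22 to -0.508), and the other 32 by -0.149 (95% interval -0.787 to 0.489). Without the 9 low arrays, cancer samples 1 to 31 differed from normal by -1.02 (95% interval -1.55 to -0.486). They then differed from the other cancer samples by -0.468 (95% interval -1.06 to 0.126), so the fall was not shown to be confined to them. Among basal keratinocyte markers none of 8 measured members passed over the list alone, with DST at 0.54 (SE 0.31) and CDH3 at 0.21 (SE 0.28). That list's mean level, 8.08, was below background, so a change in transcripts too dim to be measured cannot be excluded.

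**Figure D1:**
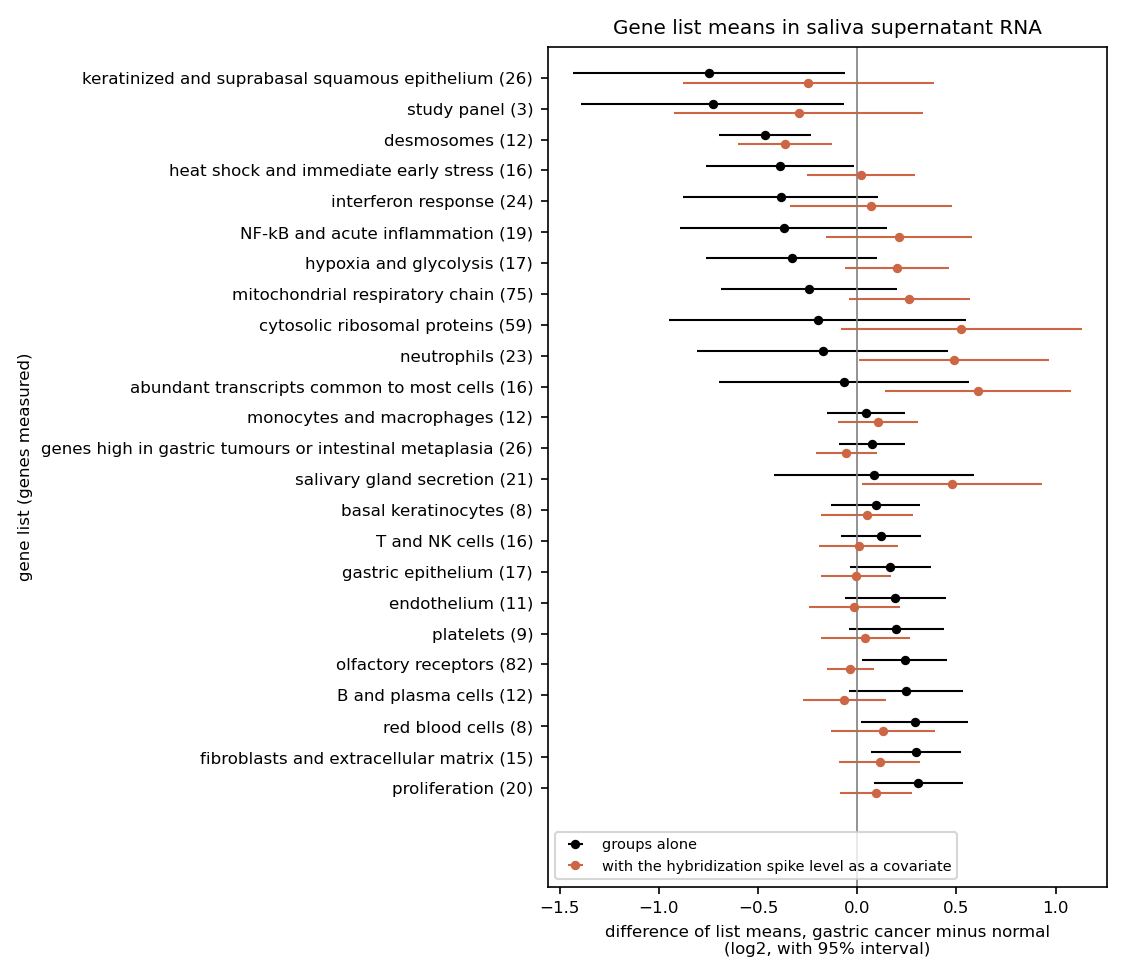
Difference of list means between gastric cancer (n = 63) and normal (n = 31) samples on the log2 scale (horizontal axis) for each of the 24 gene lists (vertical axis, with the number of genes). Points are estimates and bars 95% intervals, in black for the groups alone and in orange with the spike level as a covariate; the desmosome interval of -0.601 to -0.128 stays below 0 with the covariate, and that of squamous epithelium, -0.88 to 0.385, includes it.

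SPINK7, PPL and SEMA4B formed the panel that the study put forward from these samples, so their direction here is not independent evidence. SPINK7, a protease inhibitor of squamous epithelium, fell by 1.41 (SE 0.47) on the log2 scale when adjusted over the list alone (adjusted p = 0.0089 by limma), and its adjusted p over all probesets was 0.219. Its intensity was 13.99 ± 2.32 (SD, n = 63) in gastric cancer and 15.41 ± 2.33 (SD, n = 31) in normal saliva, with an area of 0.275 (95% interval 0.163 to 0.388). PPL, periplakin, differed by -0.7 (SE 0.46) and SEMA4B, a semaphorin, by -0.07 (SE 0.36), and neither passed. SEMA4B was below background in both groups, at 7.55 and 7.62. Camera called the panel lower with an adjusted p of 0.0409, a call lost with an estimated correlation (adjusted p = 0.268). The difference of the panel's means was -0.729 (95% interval -1.39 to -0.0676) and was -0.296 (95% interval -0.924 to 0.332) with the spike level as a covariate. It was -1.18 (95% interval -2.04 to -0.321) in cancer samples 1 to 31 against normal and -0.293 (95% interval -0.94 to 0.354) in the other 32. Without the arrays whose abundant transcripts were low, cancer samples 1 to 31 differed from normal by -0.904 (95% interval -1.5 to -0.306). Their difference from the other cancer samples was then -0.21 (95% interval -0.79 to 0.37), against -0.885 with all arrays. The panel's fall was therefore not shown to be confined to cancer samples 1 to 31.

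**Figure D2:**
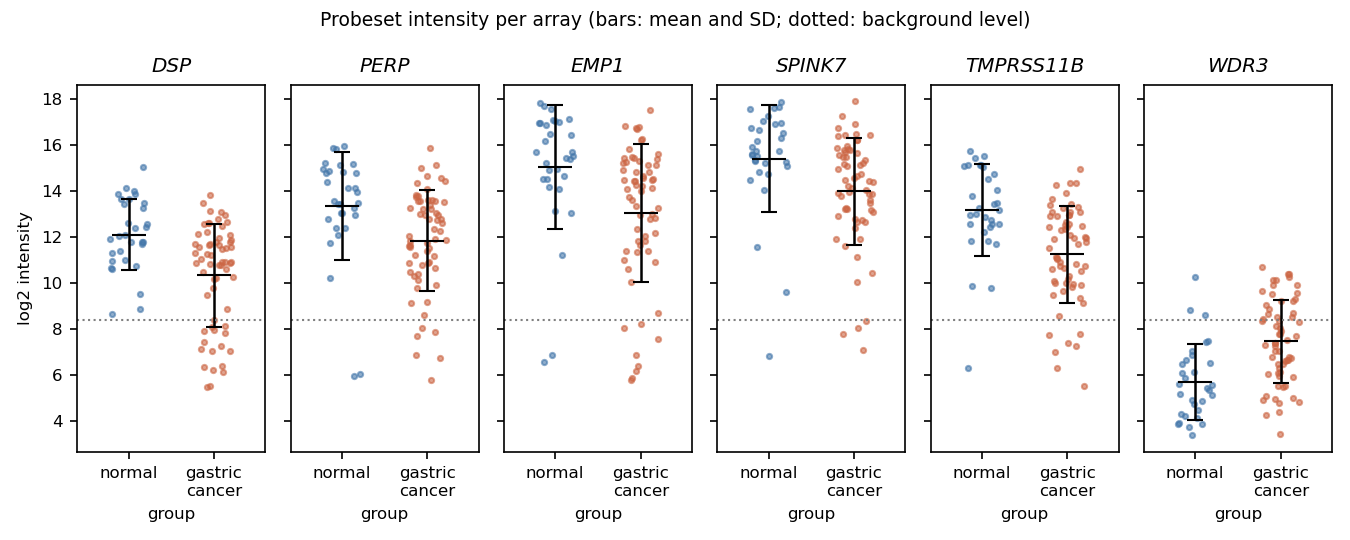
Log2 intensity (vertical axis) of 6 probesets in each normal and gastric cancer array (horizontal axis), with dots for arrays, bars for the mean and SD, and a dotted line at the background level of 8.41. The groups overlap for each gene shown; the DSP mean is 10.33 in gastric cancer and 12.1 in normal saliva, and both WDR3 means lie below the dotted line.

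Camera called 6 lists of general cell programmes lower, and each of these calls was lost with an estimated correlation (adjusted p = 0.268 to 0.785). Proliferation genes, with a median of 0.286, were not called. In the heat shock and immediate early list, BAG3 and the chaperone gene HSPH1 fell when adjusted over the list alone, with log2 differences of -1.56 (SE 0.37) and -1.11 (SE 0.34), and the other 14 of 16 did not pass, with HSPB1 at -0.89 and PPP1R15A at 0.64. Of the 3 HSPH1 probesets, 2 were higher in gastric cancer. Camera's adjusted p was 0.00113 and was 0.268 with an estimated correlation. The difference of the list's means was -0.391 (95% interval -0.764 to -0.0172) and was 0.0189 (95% interval -0.251 to 0.289) with the spike level as a covariate. In the hypoxia and glycolysis list, BNIP3, a mitophagy receptor, fell by 1.42 (SE 0.43) and 16 of 17 did not pass, with PFKFB3 at -0.93, ADM at -0.79 and ENO1 at 0.79, where 3 of 4 ENO1 probesets were lower. Its adjusted p was 0.00763, and 0.448 with an estimated correlation. None of 24 interferon response genes passed, with RSAD2 at -1.5, IFIT1 at -1.34, CXCL10 at -1.04 and HERC5 at -0.81. The list's median was -0.317 (camera adjusted p = 0.00168, adjusted p = 0.448 with an estimated correlation). None of 19 inflammatory genes of the NF-kB list passed, with PTGS2 at -1.05, NFKBIZ at -1, CCL4 at -0.61 and TNF at 0.63. Its median was -0.472 (adjusted p = 0.0022, and adjusted p = 0.448 with an estimated correlation).

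None of 75 genes of the mitochondrial respiratory chain passed, with NDUFA6 at -0.95, SDHA at -0.77, NDUFS3 at 0.92 and CYC1 at 0.89. The list's median was -0.25 (camera adjusted p = 0.000126, adjusted p = 0.519 with an estimated correlation). None of 59 ribosomal protein genes passed, with RPS25 at -0.88, RPL31 at -0.78, RPL8 at 0.84 and RPL3L at 0.61. Their median was -0.248 (adjusted p = 0.00763, and adjusted p = 0.785 with an estimated correlation), and relative to all genes it turned from -0.344 to 0.134 after quantile normalization. With the spike level as a covariate the shifts of the hypoxia, interferon, inflammatory, mitochondrial and ribosomal lists turned positive. In the list of abundant transcripts none of 16 passed and camera made no call (adjusted p = 0.421), with PPIA at -0.6 and FTL at 0.53. Its shift of -0.145 was 0.59 with the spike level as a covariate (adjusted p = 4.24e-07, and adjusted p = 0.372 with an estimated correlation), and the difference of its means went from -0.0657 to 0.608 (95% interval 0.138 to 1.08).

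Among white blood cells, neither neutrophil nor other markers passed over their lists alone. Neutrophil markers went both ways, with NAMPT at -1.3 (SE 0.47) and the oxidase subunit CYBB at 0.87 (SE 0.32), and none of 23 passed (camera adjusted p = 0.187). The list's shift turned from -0.369 to 0.399 with the spike level as a covariate (adjusted p = 6.37e-06, and adjusted p = 0.533 with an estimated correlation), and the difference of its means from -0.175 to 0.487 (95% interval 0.0102 to 0.964). None of 12 monocyte and macrophage markers passed, with MS4A7 at -0.95 and CSF1R at 0.84 (adjusted p = 0.993). None of 16 T and NK cell markers passed, with TRAT1 at 0.97 and CD3D at 0.64 (adjusted p = 0.848), and none of 12 B and plasma cell markers, with POU2AF1 at 0.81 and MZB1 at 0.66 (adjusted p = 0.336). The T and NK list and the B and plasma list had mean levels below background, at 7.67 and 7.97. A change in transcripts too dim to be measured cannot be excluded for them. MS4A7 and CSF1R also lay below background in both groups. None of 21 salivary gland secretion genes passed, with PIP at -0.84 (SE 0.41) and PRB3 at 0.77 (SE 0.38) (adjusted p = 0.905). The list's shift of 0.035 was 0.399 with the spike level as a covariate (adjusted p = 0.000109, and adjusted p = 0.533 with an estimated correlation), where the difference of its means was 0.476 (95% interval 0.0219 to 0.93), and -0.338 with the sample number as a covariate (adjusted p = 0.0321, and adjusted p = 0.415 with an estimated correlation).

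Transcripts of the stomach and its tumours were not detectably different. None of 17 gastric epithelial genes passed, with the mucin genes MUC5AC at 0.73 (SE 0.3) and MUC6 at 0.88 (SE 0.36) (camera adjusted p = 0.547). None of 26 genes high in gastric tumours or intestinal metaplasia passed, with CEACAM5 at -0.81 (SE 0.33) and CEACAM6 at -0.75 (SE 0.38) (adjusted p = 0.993). The difference of the tumour list's means was 0.0747 (95% interval -0.0939 to 0.243). Both lists had a mean level below background, at 8.06 for gastric epithelium and 8.18 for the tumour list. Their comparison therefore cannot exclude a change in transcripts too dim to be measured. CEACAM5 and CEACAM6 were above background in normal saliva too, with means of 9.86 and 12.42.

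Several dim lists held 1 to 3 members that rose when adjusted over the list alone. These included the cell cycle genes CDK1 by 1.14 (SE 0.33) and MCM6 by 1.23 (SE 0.37) with 17 of 20 proliferation genes not passing, the collagen gene COL5A1 by 1.23 (SE 0.34) among 15 fibroblast genes, with 2 of 3 COL5A1 probesets higher and FAP at 0.87, and the red cell membrane gene EPB42 by 0.94 (SE 0.33) among 8 red blood cell genes, with HBM at 0.85. Camera called none of these lists, at adjusted p = 0.0617, 0.142 and 0.292. The means of MCM6, COL5A1 and EPB42 lay below background in both groups, and so did the normal mean of CDK1, 7.63. None of 11 endothelial genes passed, with TEK at 0.99 and TIE1 at 0.78 (adjusted p = 0.521), nor any of 9 platelet genes, with ITGA2B at 0.65 and PF4 at 0.59 (adjusted p = 0.521). Both of these lists averaged below background, at 8.17 and 7.53. The olfactory receptors, which mark background, moved the same way. OR2A4 rose by 1.58 (SE 0.37), the other 81 of 82 did not pass, with OR5P3 at 0.83, OR10C1 at 0.75 and OR5P2 at 0.69, and camera called the list higher (adjusted p = 0.0349, adjusted p = 0.476 with an estimated correlation). Its median was 0.272, a shift of 0.176 relative to all genes, and with the spike level as a covariate that shift was -0.057.

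The arrays themselves differed between the groups. The hybridization control spikes averaged 17.81 ± 0.7 (SD, n = 63) in gastric cancer and 17.34 ± 0.749 (SD, n = 31) in normal samples, a log2 difference of 0.471 (95% interval 0.159 to 0.783) with a permutation p of 0.00345, or 0.0166 adjusted over 8 array measures. The array median was higher by 0.129 and the 95th percentile differed by -0.191, both with an adjusted p of 0.0166. The 3-prime to 5-prime difference of ACTB was 6.27 in gastric cancer and 7.18 in normal samples (adjusted p = 0.124) and that of GAPDH was 4.14 and 4.37 (adjusted p = 0.572). Within both groups a higher spike level went with higher olfactory receptor signal, with Pearson r of 0.854 (permutation p = 0.0001) and Spearman rho of 0.852 (p = 0.0001) in gastric cancer and r of 0.851 (p = 0.0001) and rho of 0.857 (p = 0.0001) in normal samples. Without the 2 arrays farthest from the median, r was 0.834 and 0.822. With squamous genes r was -0.479 (p = 0.0002) and rho -0.385 (p = 0.002) in gastric cancer, and r was -0.487 without the 2 farthest arrays. In normal samples r was -0.496 (p = 0.004) and rho -0.301 (p = 0.105), and r was -0.18 without the 2 farthest arrays, so it rested on them. With desmosomes r was -0.373 (p = 0.0025) and rho -0.386 (p = 0.0018) in gastric cancer, and r was -0.448 without the 2 farthest arrays; in normal samples r was -0.0959 (p = 0.612) and rho -0.136 (p = 0.468), and r was 0.134 without them. With the abundant transcripts r was -0.737 and rho -0.848 in gastric cancer and -0.659 and -0.673 in normal samples (p = 0.0001 for each), and r was -0.742 and -0.592 without the 2 farthest arrays. Over the 8 relations computed, the adjusted p of r was 0.0002 for the olfactory receptors and the abundant transcripts in both groups, 0.00032 in gastric cancer and 0.00457 in normal samples for the squamous genes, and 0.00333 and 0.612 for desmosomes. A p of 0.0001 is the smallest that 10000 resamples can give.

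**Figure D3:**
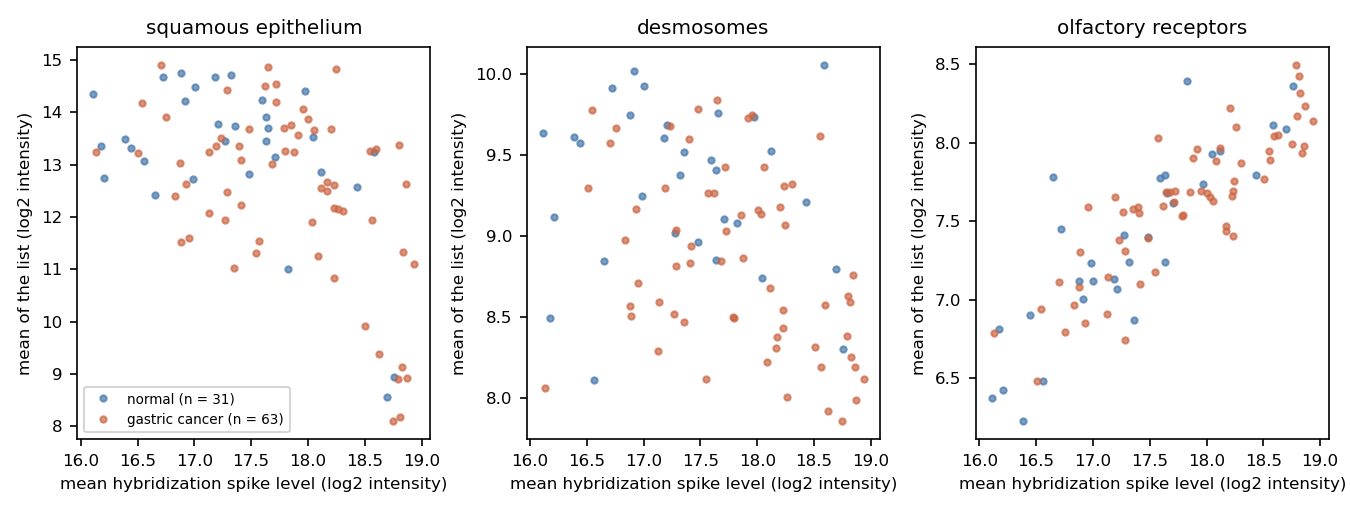
Mean hybridization spike level of each array (horizontal axis, log2 intensity) against its mean over the squamous, desmosome and olfactory receptor lists (vertical axes, log2 intensity), with 1 dot per array, blue for normal (n = 31) and orange for gastric cancer (n = 63). Olfactory receptor signal rises along the spike level in both groups, with r of 0.854 and 0.851, and the lowest squamous means lie at the highest spike levels.

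A classifier trained and judged on separate samples ranked a cancer sample above a normal one with an area of 0.635 on held-out samples (SD over repeats 0.0232). Permuted labels gave a mean of 0.486 and a highest of 0.664, and the permutation p was 0.0198. The area was 0.572 with 10 probesets and 0.672 with 100, and array summary measures in place of probesets, chosen before any values were seen, gave 0.635. The hybridization spike level alone, which carries no human transcript, gave 0.677, a measure chosen after seeing the data.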

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

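The tests with the hybridization spikes as a covariate were chosen after the results were seen, as were the spline fits, the fits with arrays left out and the squamous against neutrophil comparison. The spikes, which no comparison of transcripts uses, were higher in gastric cancer than in normal arrays by 0.471 log2 units, a signal outside the main measurement. Since the arrays were scaled to 1 mean, a higher spike level is the reading expected of less labelled human material on the array. Over the probesets other than controls, the array median was higher by 0.129 in gastric cancer and the 95th percentile differed by -0.191. Both had an adjusted p of 0.0166 by the permutation test. The Alu repeat, ribosomal RNA and abundant transcript signals did not differ detectably between the groups. The log2 difference was -0.0256 (95% interval -0.37 to 0.32) for the Alu repeat probeset (permutation p = 0.89). It was -0.3 (95% interval -0.83 to 0.23) for a ribosomal RNA probeset (permutation p = 0.27). For the mean over abundant transcripts it was -0.0657 (95% interval -0.697 to 0.565, permutation p = 0.84). The Alu and ribosomal RNA measures were not planned. These intervals are wide, and the signals come from arrays scaled to 1 mean. They therefore cannot decide whether there was less human material in gastric cancer.

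More probesets than chance gives had an unadjusted p under 0.05, and 3 of 100 splits of the samples, the real one included, gave as many as the real 6472, with 6717 the highest of the others, a share under 0.05. Over the 99 random splits the 95th percentile was 5004, and the count correlated at 0.768 with the absolute difference in spike level. That difference was at most 0.385 in them, against 0.471 in the real split, so the share does not separate the groups from the spike level. No probeset was called at the adjusted threshold by limma, and a count of 0 is reached by 100 of the 100 splits whatever the data, so it tests nothing; the highest of the other splits was 2. With the spike level as a covariate the count was 3271, against a 95th percentile of 3222 over random splits in the same model. That percentile has a bootstrap interval of 2993 to 3309, so the count lay within the spread of that bound, and 6 of the 100 splits gave as many.

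The means of the desmosome and squamous lists were lower in gastric cancer, with permutation p adjusted over 24 lists of 0.0036 and 0.12, so that the squamous list did not pass. Chance could not be excluded for the number of lists that camera called, since 15 of the 100 splits called as many as the real 10, with 13 the highest of the others. For the squamous list, a general fall of bright transcripts is left undecided. Its median lay at percentile 0.05 of lists matched on mean level. Those lists were drawn gene by gene, while the squamous genes vary together (estimated inter-gene correlation 0.519), so this percentile cannot decide it. Less human RNA stays open, since the difference was -0.247 with a linear spike term and -0.326 with a spline, with intervals that include 0, and -0.506 (95% interval -0.978 to -0.0349) without the 24 arrays with the highest spikes. It was -0.754 (95% interval -1.22 to -0.291) without 9 arrays whose abundant transcripts were low, 8 of them among those 24. A lower share of epithelial RNA also may account for it, with squamous minus neutrophil means at -0.571 (95% interval -1.1 to -0.0403, permutation p = 0.0349). RNA shortening was left undecided: its measure, the 3-prime to 5-prime difference, was not higher in gastric cancer (ACTB 6.27 against 7.18, GAPDH 4.14 against 4.37), so the fit with it as a covariate, at -0.475 here and -0.409 for desmosomes, cannot test more shortening in gastric cancer.

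For the desmosome list, the spike level as the whole cause is argued against by -0.365 with a linear term, -0.392 with a spline and -0.34 without those 24 arrays, with intervals below 0, although within the cancer group desmosome means and spike levels correlated at -0.373. RNA shortening stays open, as for the squamous list. A change of transcripts of like brightness stays open, since the list's median lay at percentile 5.79 of matched lists. No biological explanation was tested for this list.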

How the results depend on the processing

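The alternatives that use the spikes, the sample number as a covariate, a limited range of numbers or a removal of arrays by their abundant transcripts were chosen after seeing the data. The count of 0 calls was kept under 11 planned and 8 added alternatives; planned ones that made calls were Welch's test with 4, the rank-sum test with 1 and the replicate block. The numbers do not pair the samples. The replicate block on the 31 shared numbers gave 313 calls, all at least 2-fold, and 57 members within lists, while the same samples without the block gave 40, all at least 2-fold, and 38 members, so part of the change came with the choice of samples; 2 normal samples correlated best with their own number. Those samples with the number as a covariate gave 342 calls, all at least 2-fold, and 49 members, and with a spline 339 and 49. All samples with the number as a covariate gave 2165 calls, 2157 at least 2-fold, 12131 unadjusted, 149 members and a salivary gland shift of -0.338, and with a spline 1196, 1195, 10359, 128 and -0.278. Adding the spike level to the number gave 0 calls, 3335 unadjusted, 12 members, 2 lists called and shifts of 0.143 for interferon, 0.0567 for NF-kB and -0.0498 for olfactory receptors. Shifts here are relative to all genes, and members are those that pass over their list alone, 24 as reported. Normal against cancer samples numbered above 31 gave 3752 unadjusted, 7 members, 4 lists called, and shifts of -0.162 for squamous and 0.246 for ribosomal genes.

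Scaling to the spikes gave 75 calls, all lower and at least 2-fold, 47 members and 5 lists called. Quantile normalization gave 3838 unadjusted, 11 members, 2 lists called and a ribosomal shift of 0.134. Fewer probesets tested gave fewer unadjusted: 1811 above background, with 1 list called and a desmosome shift of -0.342 that was no longer called, 3169 in the brighter 27259 probesets and 2407 with 1 probeset per gene. The estimated correlation and fry each called 1 list and not the squamous one, whose shift was -0.807; fry tests against no change, and the list's median was -0.711. With the spike level as a covariate there were 3271 unadjusted, 12 members and shifts of 0.158 for NF-kB, 0.59 for abundant, 0.461 for ribosomal, 0.144 for hypoxia, 0.0112 for interferon, 0.246 for mitochondrial, 0.399 for neutrophil and -0.057 for olfactory genes. After quantile normalization with that covariate these were 3121, 10, 0.134, 0.613, 0.465, 0.25, 0.105, 0.286, 0.389 and -0.0821. With the first principal component there were 3441 unadjusted, and shifts of 0.115 for NF-kB, 0.57 for abundant, 0.458 for ribosomal, 0.0823 for hypoxia, 0.195 for mitochondrial, 0.387 for neutrophil and -0.0366 for olfactory genes. Arrays above the median spike level gave 2490 unadjusted, 1 member, a squamous shift of -0.0895 that was not called, and 0.355 for NF-kB, 0.618 for abundant, 0.4 for ribosomal, 0.358 for hypoxia, 0.0365 for interferon, 0.175 for mitochondrial, 0.581 for neutrophil and -0.059 for olfactory genes. Arrays below it gave 3786 unadjusted, 6 lists called and a ribosomal shift of -0.0414, and all but the 24 arrays with the highest spikes gave 4294, 12 members, 5 lists and 0.0403. Without the 9 arrays whose abundant transcripts were low there were 103 calls, all at least 2-fold, and 49 members, and 59, all at least 2-fold, and 49 with a bound of 3 median absolute deviations. Without those 9 arrays, quantile normalization gave 4 calls, both lists of the 2 called being squamous and desmosome genes, and a ribosomal shift of 0.0235; the spike level as a covariate gave 0 calls, 3213 unadjusted, 13 members, 3 lists called and shifts of -0.0144 for ribosomal, 0.0534 for mitochondrial and -0.00828 for olfactory genes; the sample number as a covariate gave 978 calls, 977 at least 2-fold, 10309 unadjusted and 95 members. The held-out area was 0.572 with 10 probesets, 0.672 with 100 and 0.677 with the spike level alone. The cause was not tested where none is named. Dim probesets limit these values, since 24.5% lay above background.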

Other observations

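The tests of the sample number and those without 9 arrays were chosen after the results were seen, and all of the fits tried with the number are given here or with the other alternatives. The numbers that the labels give within each group have no stated meaning. The 31 cancer samples that share numbers with the normal ones gave 40 calls against normal by limma, 14 higher and 26 lower, the other 32 gave 0 (3752 at an unadjusted p under 0.05), and the 2 sets of cancer samples gave 0 against each other (5316 unadjusted). Normal samples numbered up to 15 gave 0 calls against the rest (4276 unadjusted). Of 100 draws of 31 cancer samples, the numbered one included, 2 gave at least 40 calls, the highest other draw gave 45, and 25 of the others gave any. Among the 40, and outside the naming rule, KLF4, an epithelial transcription factor, stood at -2.49 (SE 0.49), beside DSP at -2.38 (SE 0.47) and TMPRSS11B at -2.45 (SE 0.5).

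Squamous genes were lower in cancer samples 1 to 31 than in the other cancer samples by a difference of -1.21 (95% interval -1.98 to -0.447), with a permutation p of 0.00216 that became 0.0518 over 24 lists and so did not pass. The difference was not confined to squamous genes: it was -1.11 (95% interval -1.94 to -0.288) for ribosomal, -0.86 (95% interval -1.52 to -0.197) for abundant, -0.819 (95% interval -1.54 to -0.0988) for neutrophil, -0.694 (95% interval -1.26 to -0.126) for salivary gland and -0.594 (95% interval -1.1 to -0.0927) for mitochondrial genes and -0.885 (95% interval -1.61 to -0.156) for the study's panel, with adjusted p of 0.0826 to 0.0861. Only 1 of 100 draws, the numbered one itself, gave a squamous difference from normal as low as -1.36, with -1.3 the lowest of the others. These draws shuffle the same cancer samples as the permutation test above, one-sided and without adjustment over the lists. They therefore add no further evidence against chance. A processing order marked by the number may play a part and cannot be told apart from other causes, since spike levels of neighbouring numbers correlated at 0.315 in the cancer group (permutation p = 0.0044) and at 0.0645 in the normal group (p = 0.295). Of cancer samples 1 to 31, 14 lay in the 24 arrays with the highest spikes, against 6 of the other 32 and 4 of 31 normal samples (Fisher's exact p = 0.0319 within the cancer group). Whether less human RNA accounts for it stays open: the difference was -0.995 (95% interval -1.69 to -0.3) with a linear spike term and -0.673 (95% interval -1.34 to -0.00974) with a spline, both below 0, and -0.361 (95% interval -1 to 0.28) without those 24 arrays. It was -0.468 (95% interval -1.06 to 0.126) without the 9 arrays whose abundant transcripts were low. Of these, 6 lay in cancer samples 1 to 31, 3 in the normal group and 0 in the other 32 cancer samples. Without them the difference was -0.214 for ribosomal, -0.113 for abundant and -0.0855 for neutrophil genes. It was -0.191 for salivary gland and -0.0777 for mitochondrial genes and -0.21 for the panel. All of these 95% intervals included 0, so much of each difference came with those arrays. The abundant list itself set which arrays were left out. No biological explanation was tested.

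With the sample number as a linear covariate, limma called 2165 probesets, which included 38 of the 76 named ones. Only 1 of 100 splits, the real one, gave as many, with 3 the highest of the others, and only 1 of 100 numberings shuffled within the groups, the real one, with 289 the highest of the others. The number therefore tracks some structure of the samples. With the spike level beside the number the count was 0. Over the 1035 higher probesets called the median log2 difference went from 1.35 to 0.916 (median SE 0.384 and 0.398), and over the 1130 lower ones from -1.54 to -0.594 (median SE 0.416 and 0.38), so the calls ended as the differences shrank; 1035 and 1124 of them pointed the same way. The list shifts relative to all genes went from -1.55 to -0.808 for squamous genes (camera adjusted p = 1.88e-13, and adjusted p = 0.231 with an estimated correlation) and from -0.425 to -0.432 for desmosomes (adjusted p = 0.00188, and adjusted p = 0.0231 with an estimated correlation) in the fit with both. Part of the differences in the number model may thus go with the amount of human RNA, and the calls were not taken as differences between the groups. Numbers above 31 exist in the cancer group alone, so the model also extrapolates for the normal samples.

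Without the 9 arrays whose abundant transcripts were low, limma called 103 probesets, all at least 2-fold and in the direction seen with all arrays. With all arrays their median absolute log2 difference was 1.41 (median SE 0.367), and it became 1.55 (median SE 0.355). Size and direction are no independent support: at such errors only large differences pass, and the 85 arrays kept are part of the full set. Of the 45 higher ones 6 had a mean above background, and of the 58 lower ones 56. Only 1 of 100 splits of the 85 arrays kept, the real one, gave as many, with 2 the highest of the others. Of 100 removals of 6 cancer and 3 normal arrays, the real one included, 2 gave as many, with 466 the highest of the others, and 20 of the others gave any call, so the count depends on which arrays are left out. With a bound of 3 median absolute deviations it was 59, after quantile normalization 4, with the spike level as a covariate 0 and with the sample number as one 978. The calls were not taken as differences between the groups.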
